A study of Mus musculus with 6 samples.

How the data were processed

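RNA from muscle of 6 mice was hybridized to 1 Affymetrix Mouse Genome 430 2.0 array each, 3 from mice labelled wild type (WT) and 3 from mice labelled SIRT6 knockout (KO). Total RNA was extracted with TriPure and labelled with biotin by the manufacturer's standard protocol, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale, to 1 decimal and never negative. A probe set is a group of short probes designed against the same transcript. The software, scaling and background correction behind these intensities are not given in the sources used here, and the array medians differ, so no step had made the medians equal. The columns carry no batch or scan date, and 0 further columns were left unused.

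Of the 45101 probe sets, 64 manufacturer's control probe sets were left out and 45037 were tested. Each intensity was taken as log2(value + 16) with no further normalization. A fold change is therefore on the log2(value + 16) scale and understates changes of dim probe sets. Group levels are given as the mean ± SD of the deposited intensities. Differences were tested with limma 3.58.1 (lmFit and eBayes, without trend or robust options, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Adjusted p-values of single probe sets below are limma's. Intervals are at the 95% level.

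Genes were named from a table that pairs the array's probe sets with the platform annotation. It gave 1 symbol for 34945 probe sets and several for 932, while 9160 were not listed there. A probe set with several symbols or none is reported by its identifier. Of the 34945 symbols, 34741 matched an entry of the mouse RefSeq gene table, used for current names and to tell which genes are Y-linked or autosomal. Genome positions are not given, because no build is named for the array values.

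The 39 gene lists were fixed before the data were examined, with 593 genes in all, of which 542 were measured. Each gene was represented by the probe set with the highest mean over the 6 arrays (18194 genes). Other probe sets of a gene could go the other way. The direction given was shared by 1 of 4 probe sets for Pdk1 and 3 of 5 for Ppargc1a. For Thrsp, Psmd4, Atf4 and Pdgfra it was shared by 2 of 3. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list's genes with all other genes, and adjusted over the lists. Camera with a correlation estimated from the arrays and fry, which tests whether a list's genes move one way on balance, were run beside it. Members were also counted when adjusted over the list alone. Control transcripts with 3' and 5' probe sets (Gapdh and Actb) served as signs of RNA quality, compared with an exact permutation test.

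The genes named were chosen by a rule. It took Sirt6, up to 12 genes in each direction with the largest change among those past the threshold, up to 4 members of each list with the lowest p, and a fixed set of metabolic and muscle genes. A gene in that set, Mstn, was not analysed here. Where a gene outside the rule is named, as some of those from the filtered test and the Y-linked genes are, the text says that it was chosen or looked at after its values were seen.

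On simulated data made from these arrays, with 100 probe sets changed at each fold size and 5 draws, the test over all 45037 probe sets recovered on average 36.6 of those changed 2-fold and 97.2 of those changed 4-fold, with 5.8 false calls. Over the 22518 probe sets above the median level the averages were 40.2 and 97.8, with 7 false calls. Camera called a shifted list in 20 of 20 draws and 2 of 760 unshifted lists. These draws had independent genes, unlike real lists. The changed probe sets were all drawn from those above the median level, and the simulated noise was the same in both groups. In the arrays themselves Scd1 (7.42-fold lower) and Ucp1 (17.5-fold lower) did not pass over all probe sets. The recovered numbers may therefore not hold for real changes of these sizes.

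Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, a filter to probe sets above the median level, a trended and robust variance, the replicate number as a block, offsets of 1 and 64, each array left out, a threshold of 0.01, a further 2-fold limit, the mean of a gene's probe sets, an estimated correlation and fry. Chosen after seeing the data were a test of autosomal genes alone and the filtered test combined with the other settings.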

Results

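Transcript levels were measured on arrays in muscle from 3 mice labelled wild type and 3 labelled knockout for SIRT6, a NAD-dependent deacylase that acts on chromatin, all on the 129SvJ background. The comparison asks which muscle transcripts differ between the labels. Xist and Y-linked transcripts, described below, part the mice in the same way, so the comparison cannot tell genotype from sex. The median intensity of an array lay between 10.8 and 15, and between 51.71% and 60.34% of its probe sets were below the offset of 16. The number of arrays limits the precision. The hybridization controls of WT replicate 1, transcripts added in known amounts, were 1.9 times those of WT replicate 2, while the other 4 arrays lay between 0.981 and 1.01 times that array. The brightest probe set reached 17905.4 in WT replicate 1 and 10099.5 to 10573.2 in the other 5 arrays.

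Sirt6 itself did not separate the groups. Its only named probe set, 1429631_at, read 19.9 ± 4.24 in WT and 18.2 ± 4.45 in KO (SD, n = 3 each), a fold of 0.953 with an interval of 0.735 to 1.24 (adjusted p = 0.947). The 3 WT values were 23.2, 15.1 and 21.3 and the KO values 22.6, 18.3 and 13.7. Whether this probe set lies inside the deleted part of the gene is not known here, so it does not check the labels, and the arrays are called WT-labelled and KO-labelled below. The sirtuin list as a whole was not shifted (median fold 0.994, camera adjusted p = 0.763), 0 members passed, over all probe sets or adjusted over the list alone, and Sirt1 read 17.2 ± 7.49 and 37.9 ± 25.1 in the same order.

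Xist, the non-coding RNA that coats the inactive X chromosome, was the only named gene past the threshold. Its probe set 1436936_s_at rose from 28.5 ± 3.54 in the WT-labelled to 1007 ± 253 in the KO-labelled arrays, 22.5-fold (adjusted p = 0.00401, n = 3 each). Probe set 1427262_at rose from 1.87 ± 1.39 to 237 ± 14.8, 14.2-fold (adjusted p = 0.00068). Both were higher in 3 of 3 KO-labelled arrays. Probe set 1436936_s_at did not pass without WT replicate 1 (adjusted p = 0.106), WT replicate 2 (adjusted p = 0.0978) or KO replicate 2 (adjusted p = 0.0694) or with an offset of 64 (adjusted p = 0.0667), and neither passed with the replicate number as a block (adjusted p = 0.209 for 1436936_s_at). The remaining Xist probe set, 1427263_at, was dim at 0.867 ± 0.416 and 9 ± 3.58 and did not pass (adjusted p = 0.524).

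Genes of the Y chromosome, looked at after the Xist values were seen, lay the other way. Of 20 Y-linked probe sets 7 reached the offset of 16 in the WT-labelled mean, and in 6 of these all 3 KO-labelled arrays were below all 3 WT-labelled arrays. Eif2s3y, which encodes a translation initiation factor subunit, read 58.5 ± 16.8 and 2.63 ± 1.5 (adjusted p = 0.0939). Uty, a histone demethylase family gene, read 25.1 ± 10.8 and 5 ± 4.25 at probe set 1426598_at (adjusted p = 0.524). None of the 20 probe sets named to Y-linked genes passed over all probe sets. Xist and Y-linked levels parted the mice exactly as the genotype labels did, and this holds beside every gene group described here.

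**Figure D1:**
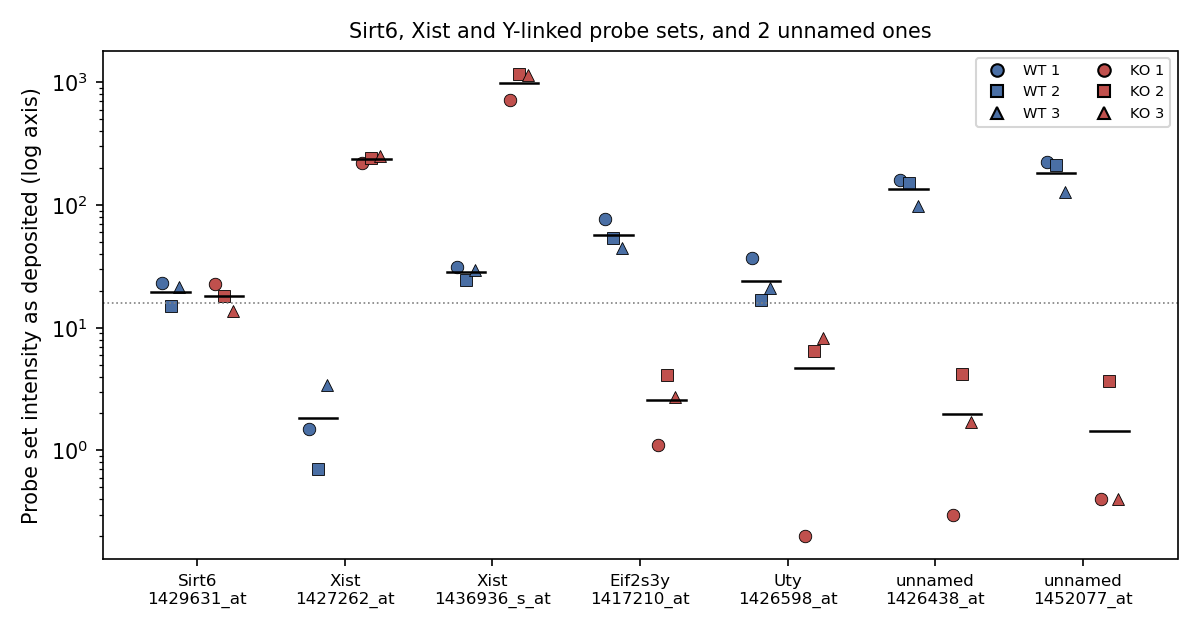
Deposited intensity (log axis) of Sirt6, Xist, Y-linked genes and the unnamed probe sets that fell, with a point for each array (blue WT-labelled, red KO-labelled; circle, square and triangle for replicates 1, 2 and 3), a black line for the group mean taken on the log2(value + 16) scale and a dotted line at the offset of 16. Sirt6 overlaps between the groups, while Xist probe set 1436936_s_at is at 24.5 to 31.3 in WT-labelled and 715.4 to 1165.7 in KO-labelled arrays.

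Over all 45037 probe sets 4 changed, 2 higher and 2 lower in the KO-labelled arrays. The 2 higher ones were those of Xist. The 2 lower ones carry no gene name here: 1452077_at fell from 188 ± 52.4 to 1.5 ± 1.91 (adjusted p = 0.0188) and 1426438_at from 137 ± 34.2 to 2.07 ± 1.98 (adjusted p = 0.0192). Like Eif2s3y they were near 0 in every KO-labelled array, at 0.3 to 4.2, and whether they are Y-linked is not known here. None of the 4 is named to an autosomal gene. At an unadjusted p under 0.05 there were 3856 probe sets, 1607 higher and 2249 lower, where chance alone gives about 2252. The 2 groups did not overlap for 12.31% of probe sets, against 10% by chance. The count was 1 without WT replicate 1, WT replicate 2 or KO replicate 2, 2 without KO replicate 3 and 6 without KO replicate 1, and quantile normalization and median centring gave 9 (3 higher, 6 lower) and 11 (3 higher, 8 lower). Restricted to probe sets named to autosomal genes, a restriction chosen after seeing the data, limma called 0 of 33588, with 2962 at an unadjusted p under 0.05.

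A filter planned before the data were examined kept the 22518 probe sets above the median level and called 79 of them, 19 higher and 60 lower. Limma was refitted to these alone, so its unadjusted p-values moved too, for Scd1 from 0.000135 to 1.27e-07 at the same change. Of the genes named here, Oxct1, Prkag3, Esr1, Kdm6a and Eif2s3y are in no list and were chosen after their values were seen. Scd1, a fatty acid desaturase, was 7.42-fold lower (filtered adjusted p = 0.000571), and Dbp, a clock output transcription factor, 4.73-fold lower (filtered adjusted p = 0.00237). Oxct1, which activates ketone bodies for use as fuel, was lower at 3 probe sets, by 3.28-fold to 3.71-fold. Prkag3, an AMPK subunit of fast muscle, was 4.26-fold lower and Esr1, the oestrogen receptor alpha gene, 3.0-fold lower. Among the 19 higher, Pdk4, a kinase that shuts off pyruvate oxidation, was 4.2-fold higher (filtered adjusted p = 0.0215), Cdkn1a, a cell cycle inhibitor, 5.67-fold higher and Egln3, an oxygen-sensing prolyl hydroxylase, 4.56-fold higher (filtered adjusted p = 0.0462). Without KO replicate 1 these 2 were 9.76-fold and 7.74-fold higher, and Cdkn1a was 3.75-fold higher without KO replicate 3. Kdm6a, an X-linked demethylase gene, was 2.46-fold higher and Eif2s3y 3.94-fold lower in the same test.

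None of the genes named from the filtered test passed over all probe sets, although Scd1 did with median centring (adjusted p = 0.0246), Scd1 and Dbp with a trended and robust variance (adjusted p = 0.00646 and 0.0148) and Egln3 without KO replicate 1 (adjusted p = 0.0114). With each array left out in turn Scd1 and Eif2s3y passed the filtered test every time, while Dbp did not without WT replicate 1 or 3, and the others named did not without WT replicate 1, WT replicate 3 or KO replicate 2, nor Egln3 and Kdm6a without WT replicate 2. The filtered count moved with single arrays, to 8 without WT replicate 1, 8 without WT replicate 3, 13 without KO replicate 2, 312 without KO replicate 3 and 1350 without KO replicate 1. It was 28 with quantile normalization, 41 with median centring, 15 and 4 with offsets of 1 and 64, and 37 with autosomal genes alone. A trended and robust variance gave 88, of which 67 were among the 79.

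Of the 39 gene lists 13 were shifted relative to the other genes by camera at the preset correlation, 6 higher and 7 lower in the KO-labelled arrays. None was called with an estimated correlation, where the lowest adjusted p was 0.816, and none by fry, whose lowest adjusted p was 0.548. No member of any list passed over all probe sets.

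Genes of muscle protein breakdown were higher in KO-labelled replicates 2 and 3. All 23 measured members of the muscle atrophy list were higher on average, with a median fold of 2.91 (camera adjusted p = 2.67e-15; adjusted p = 0.816 with an estimated correlation). Of these, 11 had all KO-labelled arrays above all WT-labelled ones, but 0 members passed, over all probe sets or adjusted over the list alone. Fbxo32, a ubiquitin ligase of wasting muscle, read 135.7, 75.9 and 55.5 in the WT-labelled and 143.7, 1296.6 and 4078.5 in the KO-labelled arrays (adjusted p = 0.556). Trim63, another such ligase, read 468.2, 408 and 285.7 against 512.1, 1825.4 and 6884.7 (adjusted p = 0.564). Ulk1, an autophagy kinase, read 101.4 ± 24.2 and 384 ± 245, and Foxo1, a transcription factor active in fasting, 69.9 ± 6.84 and 171 ± 74.3. The list's median log2 distance from the WT-labelled mean was 0.26, 1.60 and 2.53 in KO-labelled replicates 1, 2 and 3, and 0.25 in WT replicate 1.

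The proteasome list had 26 of 26 members higher on average, with a median fold of 1.41 (camera adjusted p = 3.89e-08; adjusted p = 0.827 with an estimated correlation) and 0 members passing, over all probe sets or adjusted over the list alone. Psmd4, a ubiquitin receptor of the proteasome, read 351 ± 73.6 and 832 ± 540. Its median log2 distances were 0.05, 0.31 and 1.27 in the 3 KO-labelled arrays and 0.26, 0.01 and -0.27 in the WT-labelled ones. The glucocorticoid response list had a median fold of 2.17, with 14 of 16 members higher (camera adjusted p = 1.97e-06; adjusted p = 0.816 with an estimated correlation) and again 0 passing either way, over all probe sets or adjusted over the list alone. Klf15, a factor induced by glucocorticoids, read 76.8 ± 32.7 and 289 ± 204, and Zbtb16 read 348 ± 158 and 1042 ± 480. Its medians were 0.10, 1.36 and 2.10 in the KO-labelled arrays and 0.53 in WT replicate 1. The p53 target list had a median fold of 1.35 with 10 of 14 higher (camera adjusted p = 0.0198; adjusted p = 0.816 with an estimated correlation) and 0 passing, over all probe sets or adjusted over the list alone. Cdkn1a read 76.9 ± 36.3 and 632 ± 483, while Ccng1 lay the other way at 2778 ± 741 and 1431 ± 588. The p53 target call was lost without WT replicate 1 (adjusted p = 0.0617). Medians of the p53 target list were 0.02, 0.26 and 1.07 in the KO-labelled arrays and 0.29, -0.04 and -0.32 in the WT-labelled ones. These lists share genes with the atrophy list: Cdkn1a of the p53 targets, and Klf15, Mt1 and Mt2 of the glucocorticoid response.

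**Figure D2:**
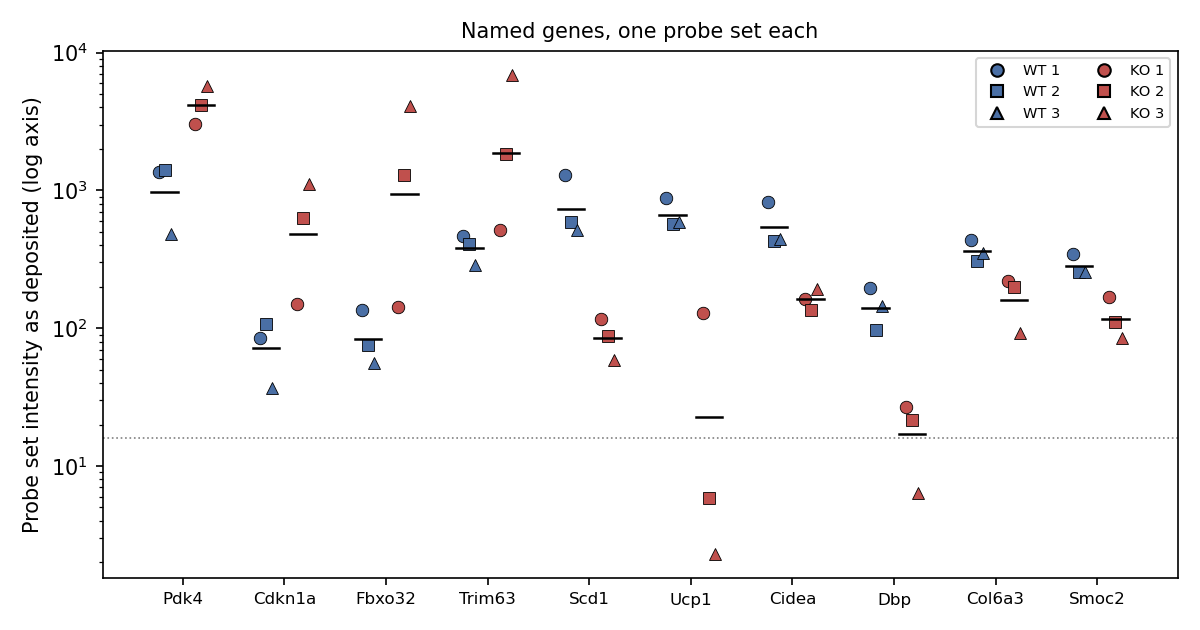
Deposited intensity (log axis) of 10 genes, with a point for each array (blue WT-labelled, red KO-labelled; circle, square and triangle for replicates 1, 2 and 3), a black line for the group mean taken on the log2(value + 16) scale and a dotted line at the offset of 16. Fbxo32 and Trim63 of KO replicate 1 lie close to the WT-labelled arrays, whereas Scd1 is at 58.9 to 116.5 in the KO-labelled and 515.7 to 1286.1 in the WT-labelled arrays.

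Genes that make lipid and cholesterol had lower median levels in each of the 3 KO-labelled arrays than in any WT-labelled one. The lipid and sterol synthesis list had a median fold of 0.632, with 16 of 19 members lower (camera adjusted p = 8.54e-07; adjusted p = 0.816 with an estimated correlation). Adjusted over the list alone 2 members fell, Scd1 and Hmgcs1, against 0 over all probe sets. Scd1 read 798 ± 424 and 87.8 ± 28.8 (n = 3 each, adjusted p = 0.289 over all), and Hmgcs1, an enzyme early in cholesterol synthesis, 262 ± 65.9 and 130 ± 10.5 (adjusted p = 0.511 over all). Thrsp, which promotes lipogenesis, read 607 ± 404 and 186 ± 68.4. Median log2 distances of the list were -0.68, -0.57 and -0.49 in the KO-labelled arrays and 0.40, -0.21 and -0.16 in the WT-labelled ones. Of the 13 measured adipose markers, brown ones included, Ucp1, Cidea, Retn and Lep were lower in every KO-labelled array (log2 changes of -4.13, -1.64, -0.86 and -0.43), Plin4 was higher in every one (1.51) and the other 8, Adipoq among them (-0.66), overlapped between the groups. Scd1 and Thrsp are abundant in fat. The adipocyte list as a whole was not shifted (camera adjusted p = 0.318).

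The fatty acid use and fasting list had 15 of 20 members higher and a median fold of 1.13 (camera adjusted p = 0.00678; adjusted p = 0.895 with an estimated correlation), with 0 passing, over all probe sets or adjusted over the list alone. Pdk4 read 1085 ± 523 and 4297 ± 1331 (adjusted p = 0.511) and Mlycd, which breaks down malonyl-CoA, 187 ± 53.2 and 435 ± 150, whereas Plin2, a lipid droplet coat gene, read 313 ± 123.1 and 157 ± 30.8. This call was lost without WT replicate 3 (adjusted p = 0.294, median log2 change -0.13) and without KO replicate 2 (adjusted p = 0.0699). The glycolysis list had 13 of 15 members lower and a median fold of 0.874 (camera adjusted p = 0.0206; adjusted p = 0.895 with an estimated correlation), with 0 passing, over all probe sets or adjusted over the list alone. Ldha, the muscle lactate dehydrogenase subunit, read 6371 ± 1306 and 3685 ± 1663, and Pfkm 3630.0 ± 551 and 3853 ± 423. The glycolysis call was lost without WT replicate 1 (adjusted p = 0.107), without KO replicate 3 (adjusted p = 0.165) and with an offset of 1 (adjusted p = 0.0548).

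Hypoxia-inducible factor targets, the gene group that SIRT6 has been linked to in glucose metabolism, went both ways. The HIF-1 list was not shifted (median fold 1.04, camera adjusted p = 0.489), with 10 of 19 members higher. P4ha1, a collagen prolyl hydroxylase, read 72.5 ± 13.5 and 25.4 ± 6.50 and was the 1 member that fell when adjusted over the list alone, against 0 over all probe sets. Egln3 read 88.7 ± 2.45 and 581 ± 377, Slc2a1, a glucose transporter, 20.5 ± 9.07 and 49.9 ± 30.6, and Hif1a 97.2 ± 3.61 and 87.6 ± 48.4. Pdk1 read 121 ± 34.7 and 112 ± 28.3. The insulin and IGF signalling list was not shifted (median fold 1.05, camera adjusted p = 0.194). In it Irs1 read 484 ± 71.2 and 257 ± 87.9, Irs2 6.80 ± 1.47 and 43.0 ± 31.4, Igf1r 123.4 ± 22.4 and 362 ± 193, and Igf1 222 ± 71.4 and 131 ± 72.3. Slc2a4, the insulin-responsive glucose transporter, read 708 ± 102 and 978 ± 202, Txnip 889 ± 119 and 1597 ± 700.3, and Ppargc1a 70.1 ± 17.3 and 79.9 ± 16.3. Oxidative phosphorylation (median fold 0.916, camera adjusted p = 0.165) and the TCA cycle (median fold 0.951, camera adjusted p = 0.622) were not shifted, although the former was called with quantile normalization (adjusted p = 0.0051), with the replicate block (adjusted p = 0.0461), without WT replicate 3 (adjusted p = 0.00238) and without KO replicate 2 (adjusted p = 0.0183). In the insulin, oxidative phosphorylation and TCA cycle lists 0 members passed, over all probe sets or adjusted over the list alone.

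Slow fibre genes were highest in KO-labelled replicate 2. The list had 10 of 12 members higher and a median fold of 2.07 (camera adjusted p = 6e-04; adjusted p = 0.816 with an estimated correlation), with 0 passing, over all probe sets or adjusted over the list alone. Myh7, the slow myosin heavy chain, read 167.7, 313 and 87.2 in the WT-labelled and 420.4, 1859.9 and 281.1 in the KO-labelled arrays (adjusted p = 0.582). Tnnc1, slow troponin C, read 137 ± 65.0 and 424 ± 328. The list's median log2 distances were 0.78, 1.97 and 0.27 in the KO-labelled and 0.05, 0.59 and -0.59 in the WT-labelled arrays, so that WT replicate 2 lay above KO replicate 3. The fast fibre list was not shifted (median fold 0.878, camera adjusted p = 0.165). Its test turned the other way with quantile normalization (adjusted p = 0.846) and without WT replicate 1 (adjusted p = 0.9, median log2 change 0.053). It was called lower without WT replicate 2 (adjusted p = 0.0305). Its Pvalb, Mylpf and Atp2a1 read 8736 ± 288, 9838 ± 650 and 10190 ± 323 in the KO-labelled arrays. In the WT-labelled arrays Pvalb read 14258.4, 8679.2 and 9520.3, Mylpf 17905.4, 10408.8 and 10285.2, and Atp2a1 16715.8, 10231.5 and 10573.2. Only WT replicate 1, whose hybridization controls were 1.9 times those of WT replicate 2, lay far above the KO-labelled arrays. These genes lie near the brightest signals, so their changes may be understated. The denervation response (median fold 1.11, camera adjusted p = 0.0576) and developmental muscle (median fold 1.10, camera adjusted p = 0.135) lists were not shifted either, and both were called higher without KO replicate 3 (adjusted p = 0.0018 for the first, without WT replicate 2 also 0.0327, and 0.000636 for the second). These 3 lists had 0 members passing, over all probe sets or adjusted over the list alone.

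Collagen and connective tissue genes were lower in the KO-labelled arrays. All 19 members of the collagen and matrix list were lower on average, with a median fold of 0.598 (camera adjusted p = 3.89e-08; adjusted p = 0.816 with an estimated correlation), and in 10 of them the groups did not overlap. None passed, over all probe sets or adjusted over the list alone. Col6a3 read 366 ± 64.7 and 171 ± 68.2, and Lum, a small collagen-binding proteoglycan, 242 ± 92.7 and 103 ± 32.8. Tendon cell genes, 8 of 8 lower, had a median fold of 0.635 (camera adjusted p = 0.00022; adjusted p = 0.816 with an estimated correlation). Cilp2, a cartilage matrix gene, read 36.4 ± 8.29 and 11.97 ± 0.451 and was the 1 member that fell when adjusted over the list alone, against 0 over all probe sets. The fibro-adipogenic cell list was not shifted (median fold 0.789, camera adjusted p = 0.0684), though called lower without WT replicate 2 (adjusted p = 0.0324), without KO replicate 2 (adjusted p = 0.0243), with the replicate block (adjusted p = 0.0286) and with the filter (adjusted p = 0.0491), and adjusted over the list alone its Smoc2 and Cxcl14 fell, against 0 over all probe sets. Smoc2 read 286 ± 51.2 and 122 ± 43.1 and Cxcl14 207 ± 77.7 and 86.4 ± 22.2, whereas Pdgfra, the surface marker of these cells, read 71.1 ± 14.1 and 108 ± 44.6. The median log2 distance of the collagen list was -0.52, -0.39 and -1.50 in the KO-labelled and 0.36, -0.29 and -0.06 in the WT-labelled arrays.

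Of 6 markers of brown fat, Ucp1 and Cidea were lower in all 3 KO-labelled arrays. Ucp1, the uncoupling protein of brown adipocytes, read 877.2, 570.3 and 586.1 in the WT-labelled and 129.9, 5.9 and 2.3 in the KO-labelled arrays (17.5-fold lower, adjusted p = 0.436 over all). Without KO replicate 1 it was 34-fold lower and passed over all probe sets (adjusted p = 0.0114), as it did with a trended and robust variance (adjusted p = 0.0193). Cidea, a lipid droplet gene abundant in brown fat, read 565 ± 224 and 164 ± 27.7 (3.12-fold lower, adjusted p = 0.384 over all). Both fell when adjusted over the list alone, against 0 members over all probe sets, while the other 4 members, Dio2 and Lhx8 among them, had log2 changes between -0.06 and -0.01. Lhx8 read 1.13 ± 0.681 and 0.433 ± 0.153, far under the offset of 16, where a change hardly shows. Dio2 was dim as well, at 23.1 ± 0.416 and 22.6 ± 5.75. The list of 6 was called (median fold 0.968, camera adjusted p = 0.0377; adjusted p = 0.816 with an estimated correlation), but not without WT replicate 3 (adjusted p = 0.121) or with an offset of 64 (adjusted p = 0.0651), and with the filter 4 members were left, too few to test. General adipocyte genes were not shifted (median fold 0.817, camera adjusted p = 0.318). Of these, adjusted over the list alone, Retn fell (69.6 ± 23.0 and 30.6 ± 8.47) and Plin4 rose (475 ± 121 and 1522 ± 835), with 0 over all probe sets, and Adipoq read 399 ± 180.2 and 249 ± 107.

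Cell division genes were slightly lower, with 15 of 19 members lower and a median fold of 0.850 (camera adjusted p = 0.00678; adjusted p = 0.816 with an estimated correlation). Ccnb2, a mitotic cyclin, read 14.1 ± 5.58 and 1.17 ± 0.379 and was the 1 member that fell when adjusted over the list alone, against 0 over all probe sets. Its level was under the offset of 16 in both groups. The call was lost without WT replicate 3 (adjusted p = 0.0505) and with the filter (adjusted p = 0.129). Interferon response genes had 13 of 16 members lower and a median fold of 0.844 (camera adjusted p = 0.0331; adjusted p = 0.816 with an estimated correlation), with 0 passing, over all probe sets or adjusted over the list alone. Psmb8, an immunoproteasome subunit, read 16.6 ± 3.56 and 4.97 ± 2.01, and Usp18 12 ± 5.27 and 2.37 ± 3.06. All these means but the first were under the offset of 16, and only 1 of the 2 Psmb8 probe sets was lower. That call was lost without WT replicate 3 (adjusted p = 0.109), without KO replicate 1 (adjusted p = 0.16), with the filter (adjusted p = 0.214), with an offset of 64 (adjusted p = 0.053) and with the mean of a gene's probe sets (adjusted p = 0.0692).

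**Figure D3:**
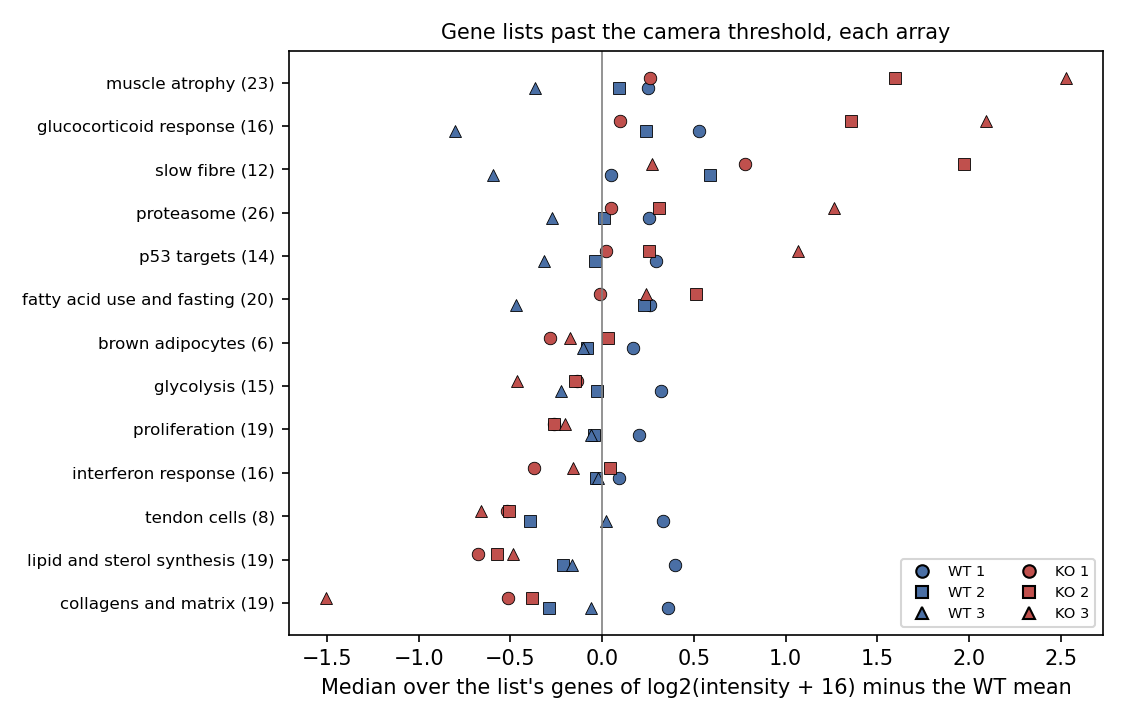
Median over each list's measured genes (number in brackets) of log2(intensity + 16) minus the WT-labelled mean, for the 13 lists past the camera threshold, with a point for each array (blue WT-labelled, red KO-labelled; circle, square and triangle for replicates 1, 2 and 3). The atrophy list is at 0.26, 1.60 and 2.53 in KO replicates 1, 2 and 3, and the lipid and sterol synthesis list lies at or below -0.49 in all 3.

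Circadian clock genes lay in both directions. The list was not shifted (median fold 1.13, camera adjusted p = 0.988), yet adjusted over the list alone Dbp and Nr1d1 fell, against 0 over all probe sets. Dbp read 145.5 ± 48.8 and 18.3 ± 10.7 (adjusted p = 0.325 over all) and Nr1d1, a nuclear receptor of the clock, 238 ± 66.8 and 86.9 ± 29.7 (adjusted p = 0.511 over all). Hlf, related to Dbp, read 34.7 ± 0.889 and 23.2 ± 2.67. Fry's test for change in either direction called this list (adjusted p = 0.0227), satellite cells (adjusted p = 0.0142) and brown adipocytes (adjusted p = 0.0227). Among satellite cell genes Myf5, a muscle lineage factor, read 5.63 ± 0.839 and 18.1 ± 2.78 and was the 1 member that rose when adjusted over the list alone, against 0 over all probe sets. Myod1 read 115 ± 47.9 and 83.4 ± 35.8, and that list was not shifted (median fold 0.976, camera adjusted p = 0.622).

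Markers of other cells in muscle were not shifted by camera. Endothelial cells (median fold 1.12, adjusted p = 0.0793), mural cells (0.925, adjusted p = 0.494), Schwann cells (1.04, adjusted p = 0.697), keratinocytes (0.990, adjusted p = 0.763) and erythroid cells (0.966, adjusted p = 0.333) had median folds between 0.925 and 1.12. Endothelial genes were called higher with the mean of a gene's probe sets (adjusted p = 0.0156), with the replicate block (adjusted p = 0.0397), without WT replicate 2 (adjusted p = 0.0128) and without KO replicate 3 (adjusted p = 0.000548). Macrophages (median fold 0.913, adjusted p = 0.374), neutrophils (0.926, adjusted p = 0.763) and lymphocytes (1.05, adjusted p = 0.906) were not shifted, and the macrophage list was called lower without WT replicate 2 (adjusted p = 0.0325). Cd163, a macrophage scavenger receptor, read 11.9 ± 1.72 and 36.9 ± 16.5, and Mrc1, another macrophage receptor, 80.2 ± 25.7 and 39.6 ± 17.5. In these lists 0 members passed, over all probe sets or adjusted over the list alone.

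Stress and growth lists were not shifted either. The median folds were 1.04 for the amino acid stress response (camera adjusted p = 0.183), 1.12 for ribosomal proteins (adjusted p = 0.208), 1.04 for ribosome biogenesis (adjusted p = 0.283), 1.02 for NF-kB targets (adjusted p = 0.873), 1.05 for heat shock proteins (adjusted p = 0.918) and 1.11 for NRF2 targets (adjusted p = 0.763). The heat shock test turned the other way with quantile normalization (adjusted p = 0.846). Ribosomal protein genes were called higher without WT replicate 1 (adjusted p = 0.000819) and NRF2 targets lower without KO replicate 3 (adjusted p = 0.0362). The median went against the direction of the test for the sirtuin, satellite cell and NRF2 target lists, and against the mean for those and for the heat shock and lymphocyte lists. Atf4, the stress response transcription factor, read 275 ± 53.03 and 589 ± 241, Tkt, a pentose phosphate enzyme, 601 ± 415 and 118 ± 30.7, and Myc 2.23 ± 0.208 and 10.7 ± 4.11, below the offset in both groups. In these lists too, 0 members passed, over all probe sets or adjusted over the list alone.

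Signs of RNA quality differed by less than the spread between arrays. The log2 difference of 3' over 5' probe sets was -0.27 ± 0.008 and -0.26 ± 0.034 for Gapdh and -0.34 ± 0.138 and -0.34 ± 0.139 for Actb in the WT-labelled and KO-labelled arrays (exact permutation p = 1 for both, two-sided, n = 3 each, where the smallest possible p is 0.1).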

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

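The settings were planned, except those on autosomal genes and those combined with the filter, which were chosen after seeing the data. The count of 4 probe sets became 9 with quantile normalization, 11 with median centring, 79 with the filter, 15 with a trended and robust variance, 1 with an offset of 64, 2 at an adjusted p under 0.01 and 0 with autosomal genes alone (2962 at an unadjusted p under 0.05), and 1 to 6 with 1 array left out. An offset of 1 gave 3 and a further 2-fold limit kept all 4. The 79 became 28 with quantile normalization, 41 with median centring, 15 and 4 with offsets of 1 and 64, 37 with autosomal genes alone and 8 to 1350 with 1 array left out. With a trended and robust variance they became 88, of which 67 were among the 79. The filter tests fewer probe sets and leaves out dim ones. Limma was also refitted to the probe sets kept, which changed the standard errors at the same log2 change. That of Ucp1 went from 0.759 to 0.538 and that of Cdkn1a from 0.698 to 0.502, while that of Xist probe set 1436936_s_at went from 0.21 to 0.248. The filtered calls therefore rest on other standard errors as well as on fewer tests. The cause of the other moves was not tested. The 13 lists became 0 with an estimated correlation and 0 with fry, and 10 to 18 with 1 array left out. With the filter 4 lists (brown adipocytes, erythroid cells, lymphocytes and keratinocytes) had fewer than 5 genes left and were not tested. Same-numbered arrays deviated with correlations of -0.005, 0.021 and -0.04 across probe sets, which showed no pairing by number. Arrays of unlike number were not compared in this way, so a weak pairing is not excluded. With the replicate block 0 probe sets passed (3367 at an unadjusted p under 0.05), 85 of the filtered ones and 16 lists. Of those 85, 59 were among the 79.

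Single lists mostly kept their direction. Outside the settings with an array left out 11 tests turned, all far from the threshold, with these median log2 changes: heat shock proteins 0.014 with quantile normalization and 0.073 with the replicate block, fast fibre -0.004 with quantile normalization, circadian clock 0.027 with the filter and 0.063 with an offset of 64, satellite cells -0.097 and neutrophils 0.125 with the filter, and circadian clock 0.101, lymphocytes -0.036, NF-kB targets -0.05 and NRF2 targets 0.054 with the mean of a gene's probe sets. With 1 array left out 20 list tests turned. The medians then ranged from -0.27 to 0.085 for the TCA cycle, -0.296 to 0.013 for oxidative phosphorylation, -0.085 to 0.327 for ribosome biogenesis, -0.262 to 0.434 for NRF2 targets, -0.134 to 0.276 for heat shock proteins, -0.051 to 0.066 for NF-kB targets, -0.029 to 0.299 for the circadian clock, -0.31 to 0.053 for fast fibre, -0.459 to -0.027 for adipocytes, -0.263 to -0.045 for macrophages, -0.02 to 0.082 for lymphocytes, -0.129 to 0.024 for neutrophils, -0.06 to 0.137 for Schwann cells and -0.094 to 0.025 for keratinocytes. Log2 changes of genes crossed 0 likewise, from -0.169 to 0.028 for Sirt6, -0.028 to 0.361 for Cd3g, -0.109 to 0.099 for Dio2, -0.103 to 0.017 for Epb42, -0.57 to 0.191 for Hif1a, -0.319 to 0.083 for Pdk1, -0.029 to 0.192 for Pfkm, -0.017 to 0.261 for Ppargc1a and -0.478 to 0.091 for Sirt4. The cause was not tested. Between 51.71% and 60.34% of probe sets per array were below the offset of 16, where changes are understated.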

Other observations

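The tests in this part were chosen after the result was seen, except the splits of the filtered count.

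Among the 79 filtered calls, several groups of genes have not been described above, and they were chosen after their values were seen. Serpinh1, a collagen chaperone, was lower at 2 probe sets, by 2.67-fold and 2.73-fold (filtered adjusted p = 0.04 and 0.0355), and Bgn, a matrix proteoglycan, was 3.04-fold lower (filtered adjusted p = 0.0322). Prkar2b, a regulatory subunit of protein kinase A, was lower at 3 probe sets, by 2.53-fold to 4.28-fold. Agpat2, an enzyme of glycerolipid synthesis, was 2.95-fold lower, Ccnd1, cyclin D1, 2.75-fold lower and Hspb6, a small heat shock protein of muscle, 2.80-fold lower. Higher ones included Peg3, an imprinted gene, at 3.81-fold (5.78-fold without KO replicate 1), Cirbp, a cold-inducible RNA-binding protein, at 2.86-fold and Rps4l, a ribosomal protein gene, at 3.53-fold (filtered adjusted p = 0.00237). With an array left out, Rps4l did not pass without WT replicate 3, and the others named here did not without WT replicate 1, WT replicate 3 or KO replicate 2, nor Peg3, Cirbp and 1 probe set each of Serpinh1 and Prkar2b without WT replicate 2. By placement 57 of the 79 were autosomal, 4 X-linked, 1 Y-linked and 17 unplaced.

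The groups were also set against all 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 4 probe sets and the highest other split 0, so 1 of the 10 splits gave as many. With the filter the real split gave 79 and the highest other 0, again 1 split. For the lists the real split gave 13 and the highest other 15, and 4 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 3856 probe sets and the highest other 5396, with WT replicate 1 and KO replicates 2 and 3 set against the rest.

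Xist and Y-linked transcripts parted the groups. A candidate explanation is that the WT-labelled mice are male and the KO-labelled mice female: all 3 Xist probe sets were higher in every KO-labelled array, and 6 of the 7 Y-linked probe sets detected in the WT-labelled mean were lower in every KO-labelled array. Whether sex in place of genotype accounts for the other differences cannot be told apart here, because 0 arrays had an Xist level on the other group's side. Apart from Xist and the Y-linked genes, genotype, sex and both together stay open for each list and gene above. They stay open for the 2 unnamed probe sets that fell as well, so the count of 4 may reflect sex alone.

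Atrophy genes differed among the 3 KO-labelled arrays, with KO replicate 1 close to the WT-labelled ones. That KO replicate 1 belongs with the 3 WT mice in sex and genotype is argued against by Xist and Y-linked probe sets, 8 of 9 detected ones lying outside the WT values by more than the WT range. That it is wild type but of the sex of KO replicates 2 and 3 cannot be told apart: on the axis from WT-labelled arrays (0) to those 2 (1) its median placement averaged 0.271 (0.238 to 0.31) and left-out WT-labelled arrays lay at 0.135 to 0.241, while its Scd1 (116.5) and its lipid list median (-0.68) lay below every WT-labelled array. A larger share of slow fibres stays open, since the slow fibre median moved against the atrophy median in 2 of the 3 pairs of KO-labelled arrays, both with KO replicate 3 (-1.76 against 0.96 from replicate 2), and with it from replicate 1 to 2 (1.16 and 1.09). RNA quality stays open as well: for Actb the largest distance of a KO-labelled array from the WT-labelled mean was 0.163, within the WT range of 0.274, but for Gapdh it was 0.034 against 0.016, and feeding, age or illness were not tested.

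Ucp1 and Cidea were lower in every KO-labelled array. Fewer adipocytes of any kind as the whole cause of lower Ucp1 is argued against by Adipoq, an adipocyte hormone gene, whose log2 change had a lower bound of -1.63, above the upper bound of -2.33 for Ucp1. For Cidea the same explanation stays open, because the Adipoq change of -0.66 (interval -1.63 to 0.31) overlaps that of Cidea (-2.29 to -0.99), and so, narrowly, does that of Fabp4 (-0.29, interval -1.01 to 0.42), while the changes were -0.09 for Cidec, -0.06 for Pparg and 1.51 for Plin4, which like Fabp4 are not made by adipocytes alone. Less brown fat in the sampled tissue may account for both, but Ucp1 then changed by -2.49 more than Cidea on the log2 scale. That gap came mainly from KO replicates 2 and 3. Ucp1 minus Cidea was -0.303, -2.793 and -3.501 in KO replicates 1, 2 and 3, and 0.089 to 0.395 in the WT-labelled arrays. The exact permutation p of 0.1 is the smallest that 3 against 3 can give. A lower activity of brown fat cells with the genotype or sex was not tested.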
